A study of Mus musculus with 14 samples.

How the data were processed

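Lineage-depleted bone marrow progenitors of C57BL/6 mice, either wild type (WT) or lacking Kdm6a (KO, the gene also called Utx), were profiled by ChIP-seq, per the labels. H3K27me3 and H3K27ac were measured in 2 WT and 2 KO libraries each, and UTX itself in 2 WT libraries. 1 IgG library, labelled as the control of a BCOR precipitation, served as background. 11 libraries entered the comparisons. 3 further samples of the series (2 inputs and a second IgG) were not used here. The labels do not state whether libraries with different numbers came from separate animals, so p-values of edgeR and DESeq2 measure the spread between libraries only. Tests across genes or regions (camera, Fisher's exact test and permutations over regions) take genes or regions as units. Their p-values do not measure the spread between libraries or animals.

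Per the submitters' processing notes, enriched stretches (islands) were called with SICER against mouse build mm10. The notes name no SICER version, aligner, gap size, threshold or control. The deposited files list each island with its counts, whole numbers of reads per island, called per library. They were checked: widths were multiples of 200 bp, and the smallest gap between islands was 800 bp for histone marks and 400 bp for UTX and IgG. Reads outside islands were not used here, so the depth given is that of reads in islands on chromosomes 1 to 19, X and Y. A region with no island in a library has no count there, which limits every comparison to what SICER called.

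Genes were taken from an NCBI RefSeq table of build GRCm38 (the assembly of mm10), limited to 21887 protein-coding genes on placed chromosomes. The table gives no strand. The promoter windows first chosen, 2 kb either side of the 5' end, were therefore replaced by windows of 2 kb either side of both annotated ends of a gene, called gene ends. A gene end was marked in a library when an island met it by at least 1 bp. It was called lost when marked in both WT and neither KO library, and gained in the reverse case. The same count was made for the 2 other ways of splitting the 4 libraries into pairs.

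For changes in signal, islands of the 4 libraries of a mark were merged where they overlapped. Regions with an island in all 4 libraries were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg threshold 0.05). Values are given as CPM (the cpm function of edgeR, over tested regions), those of islands at gene ends as rpm (the same scale over all island reads of a library), mean ± SD of 2 libraries, and log2 fold changes are KO over WT with a standard error (SE) taken from the F statistic. A gene's region is the strongest tested region at its ends, and neighbours can share a region. Recovery was tested on fully simulated counts, drawn from the mean of each region, the library sizes and the common dispersion of all regions. Differences in spread between regions and effects of island calling were not simulated, so recovery in the real data can differ. Of 100 H3K27ac regions changed 2-fold 75% were recovered, and of those changed 4-fold 100%, with 11 of 18620 unchanged regions called. For H3K27me3 the values were 15%, 94% and 5 of 6571.

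16 gene lists were fixed, with 342 distinct genes, of which 1 was not matched: ETS family factors, GATA and erythroid, megakaryocyte, granulocyte and monocyte, stem cell, B cell, T and NK cell, dendritic cell, basophil and mast cell, stromal and endothelial, leukaemia, Hox, developmental Polycomb target, COMPASS with PRC2 and coactivator, AP-1 with NF-kB and interferon, and housekeeping genes. Lists with at least 3 tested regions were compared with other regions by camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation). Lost and gained members were compared with other genes by Fisher's exact test. Both were adjusted over the lists. Overlap of lost and gained gene ends between the marks was tested by Fisher's exact test.

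A gene end was UTX occupied when it met an island of both UTX libraries and no IgG island. The mean log2 fold change of UTX-occupied regions was compared with that of other regions within 10 bins of mean log2 CPM by 100000 permutations of the UTX label (two-sided, smallest possible p 1e-05). Regions and genes are not independent replicates in these tests.

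Named genes followed a rule: members of the lists, the 10 strongest gene ends lost or gained per mark, up to 10 genes per direction with the largest edgeR change and no overlap between WT and KO libraries, the 10 strongest UTX-occupied gene ends, and Kdm6a, Kdm6b and Uty. The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined. Alternatives covered a stricter island threshold, equal list lengths, windows of 1 kb and 5 kb, an island covering at least 50% of the window, autosomes only, DESeq2 1.42.0, scaling to total island reads, regions with an island in at least 2 libraries, at least 50 reads in every library, islands merged within 1 kb, a replicate block, reads per covered length, and leaving out each library. Chosen after seeing the data were whole gene spans, leaving out regions at IgG islands, per covered length for the UTX and list comparisons, and lists without each library. A comparison of ETS, GATA, RUNX and CEBP sequence motifs was not run, since no genome sequence was used here. Python 3.11.15 with NumPy, pandas, SciPy, numba and matplotlib did the remaining work.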

Results

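H3K27ac, H3K27me3 and UTX islands were compared in lineage-depleted bone marrow progenitors of WT and Kdm6a KO mice. Each histone mark had 2 WT and 2 KO libraries, UTX had 2 WT libraries, and 1 IgG library gave the background. H3K27ac libraries held 9330823 and 15256696 reads in islands (WT replicates 1 and 2) and 14763744 and 11121847 (KO). H3K27me3 libraries held 2743508, 2455803, 2347442 and 2507004 in the same order. The UTX libraries held 816567 and 1834418, and the IgG library 154029. H3K27me3 islands numbered 19629.5 ± 1107 in WT and 15204 ± 762 in KO (mean ± SD, n = 2 each, ratio 0.774), covering 106.4 ± 15.9 and 86.2 ± 13.2 Mb. H3K27ac islands numbered 30914.5 ± 1771 and 28313 ± 2588. An exact permutation test gave 0.333 for the H3K27me3 islands, the smallest possible with 2 libraries per group, and 0.667 for the H3K27ac islands.

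Kdm6a, the gene removed in KO, was read first as a check of the labels. Its gene (chromosome X, 18160862 to 18279936, mm10) held H3K27ac islands in all 4 libraries, with 1840 and 1562 reads in WT and 2674 and 2059 in KO. The region at its end did not pass the test (148.2 ± 54.6 to 164.9 ± 4.03 CPM, log2 fold change 0.16, SE 0.217, edgeR adjusted p = 0.623). No H3K27me3 island and no IgG island met the gene, while UTX itself lay there with 181 and 403 reads in the WT libraries. Island lists show a deleted exon only where a gap falls on it, so the genotype labels were not checkable from Kdm6a. Its paralogue Kdm6b (chromosome 11, 69398508 to 69420367) also did not pass in H3K27ac (log2 fold change 0.24, SE 0.101, edgeR adjusted p = 0.133), and Uty held no island in any of the 11 libraries.

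H3K27ac fell at erythroid genes and rose at B cell genes in KO progenitors. Tal1, which builds the GATA complex on erythroid enhancers, fell from 389.5 ± 12.9 to 122.1 ± 15.9 CPM in a region shared with Stil (log2 fold change -1.67, SE 0.103, n = 2 and 2, edgeR adjusted p = 0.00025). Ets1, an ETS factor of lymphoid and endothelial cells, rose from 104.3 ± 13.02 to 327.8 ± 8.27 CPM (1.66, SE 0.101, adjusted p = 0.00025). In all, 4889 of 18820 tested regions differed, 2258 higher and 2631 lower, by more than 2-fold in 840 and 1069 of them. The largest fall at a gene end was at Slc22a23, an organic ion transporter (252.2 ± 56.1 to 14.4 ± 2.74 CPM, -4.12, SE 0.198). Specc1 (-3.53), the sodium pump subunit gene Atp1b2 with its neighbour Shbg (-3.31, 1 region), Mindy4 (-3.31), the sterol exporter gene Abcg4 (-3.30), the asparagine synthetase gene Asns (-3.27), Phyhip (-3.20) and Cnn3 with Slc44a3 (-3.19, 1 region) followed. The largest rise was at the transporter gene Slco4c1 (6.63 ± 4.76 to 53.05 ± 0.20 CPM, 3.06, SE 0.431). Rises followed at Chst3 (2.79), the calcineurin subunit gene Ppp3cc (2.77), Ncam1 (2.49), Il5ra, the interleukin 5 receptor of eosinophils (2.46), the B cell coactivator Pou2af1 (2.38), Mylk (2.37), Adm2 (2.34), the death receptor Fas (2.32) and Irf4 (2.31).

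The 2 other ways of pairing the H3K27ac libraries gave 0 called regions with edgeR (105 and 93 at an unadjusted p under 0.05, against 7223 for the genotypes). Each of them puts 1 WT and 1 KO library on either side, so the genotype difference widens their spread and holds such counts down. DESeq2 called 2099 higher and 2454 lower. Testing regions with islands in at least 2 libraries ended the calls of 21 of 88 genes named here, among them Cd34, Mecom, Meis1, Flt3, Lck, Cd3d, Clec1b, Elk3 and Cd14. Without WT replicate 1 the counts were 1324 and 1739, without WT replicate 2 they were 1254 and 1395, and without KO replicates 1 and 2 1343 and 1979, and 1423 and 2022. Reads per covered length gave 79 higher and 259 lower calls, a larger share of lower calls than whole islands gave. The median log2 fold change of all tested regions was -0.071 on that scale, against 0 over whole islands. Signs and calls there are therefore shifted downwards, and a small negative value need not lie below that of most regions. Of the 88 genes, 21 kept their call on that scale, among them Tal1, Epor, Car2, Zfpm1, Slc22a23 and Irf4. Ets1 (0.46, adjusted p = 0.0987), Slco4c1 (0.49, adjusted p = 0.336) and Fas (0.10, adjusted p = 0.874) kept their sign but not their call, as did Atp1b2 (-0.96, 0.0858), Mindy4 (-1.07, 0.0698), Asns (-0.68, 0.275), Cnn3 (-0.56, 0.318), Mylk (0.37, 0.441) and Adm2 (0.92, 0.109), and Ppp3cc (-0.11) lost its sign. Regions lower in KO lay at gene ends in 60.1% of cases, those higher in 49.7%, and all tested regions in 54.0%.

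All 17 tested regions of the GATA and erythroid list fell in H3K27ac, with a median log2 fold change of -1.25 (17 lower also when adjusted over the list alone). The GATA factors themselves fell: Gata1 from 91.8 ± 5.16 to 42.8 ± 0.16 CPM (-1.10, SE 0.106, edgeR adjusted p = 0.000777) and Gata2 from 225.9 ± 18.8 to 140.9 ± 38.6 (-0.68, SE 0.173, adjusted p = 0.0287). Gata2, which keeps stem and mast cell programs, lost its call without WT replicate 1 (adjusted p = 0.171), WT replicate 2 (0.106) or KO replicate 2 (0.0542), and with islands in at least 2 libraries (0.139). Their partners fell as well: Zfpm1, encoding the cofactor FOG1 (728.7 ± 104.6 to 305.7 ± 54.0 CPM, -1.25), Lmo2 (-0.76), Ldb1 (-0.68), Lyl1 (-0.41) and the erythroid repressor Gfi1b (329.8 ± 14.3 to 99.6 ± 21.0 CPM, -1.73). Klf1, the activator of globin genes, fell by 1.11 and Nfe2 by 0.47. Other genes of the red cell program fell too: Epor, the erythropoietin receptor (65.9 ± 2.35 to 10.7 ± 1.77 CPM, -2.62), Sptb (-2.47), Ermap (-2.40), the carbonic anhydrase gene Car2 (-1.87), Hbb-bt (-1.77) and the transferrin receptor gene Tfrc (-0.69). The list passed camera (two-sided, adjusted p = 5.03e-27, and 1.09e-10 per covered length with a median of -0.89), but not with an estimated correlation (adjusted p = 0.389 with an estimated correlation). Per covered length 10 of the 17 regions stayed lower. Ermap was near 0 there (-0.02, adjusted p = 0.985), and Gata1 (-0.89, 0.0723), Gata2 (-0.59, 0.0856), Klf1 (-0.78, 0.0763), Lyl1 (-0.23, 0.261) and Tfrc (-0.26, 0.47) lost their calls.

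Megakaryocyte genes fell in 7 of 11 regions and rose in 1 (8 lower and 1 higher when adjusted over the list alone). Vwf, encoding von Willebrand factor, fell from 201.8 ± 4.36 to 40.8 ± 0.32 CPM (-2.31, SE 0.087, edgeR adjusted p = 0.000171). The platelet glycoprotein genes Gp5 (-2.12) and Gp9 (66.6 ± 5.14 to 18.4 ± 2.53 CPM, -1.86) fell, as did Thbs1 (-1.35), Clec1b (-0.72) and Itga2b (-0.63). Clec1b lost its call without WT replicate 2 (-0.44, adjusted p = 0.149) or KO replicate 2 (0.105), and Itga2b without WT replicate 1 (0.0763), WT replicate 2 (0.0671) or KO replicate 2 (0.0711). The region that Selp, encoding P-selectin, shares with F5 rose (33.1 ± 3.87 to 95.7 ± 16.01 CPM, 1.52). Itgb3 (-0.06), Gp1ba (-0.13) and the platelet factor genes Pf4 and Ppbp (-0.76, adjusted p = 0.0556) did not pass. Camera gave an adjusted p of 1.03e-05 (adjusted p = 0.389 with an estimated correlation). Per covered length the list did not pass (adjusted p = 0.974, median 0.04 against -0.72), and Vwf (0.20) and Thbs1 (0.15) changed sign without passing, while Itga2b passed as higher (1.06). Gp5 (-0.964, edgeR adjusted p = 0.0646), Clec1b (-0.154, 0.808) and Selp (0.953, 0.0753) lost their calls on that scale.

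**Figure D1:**
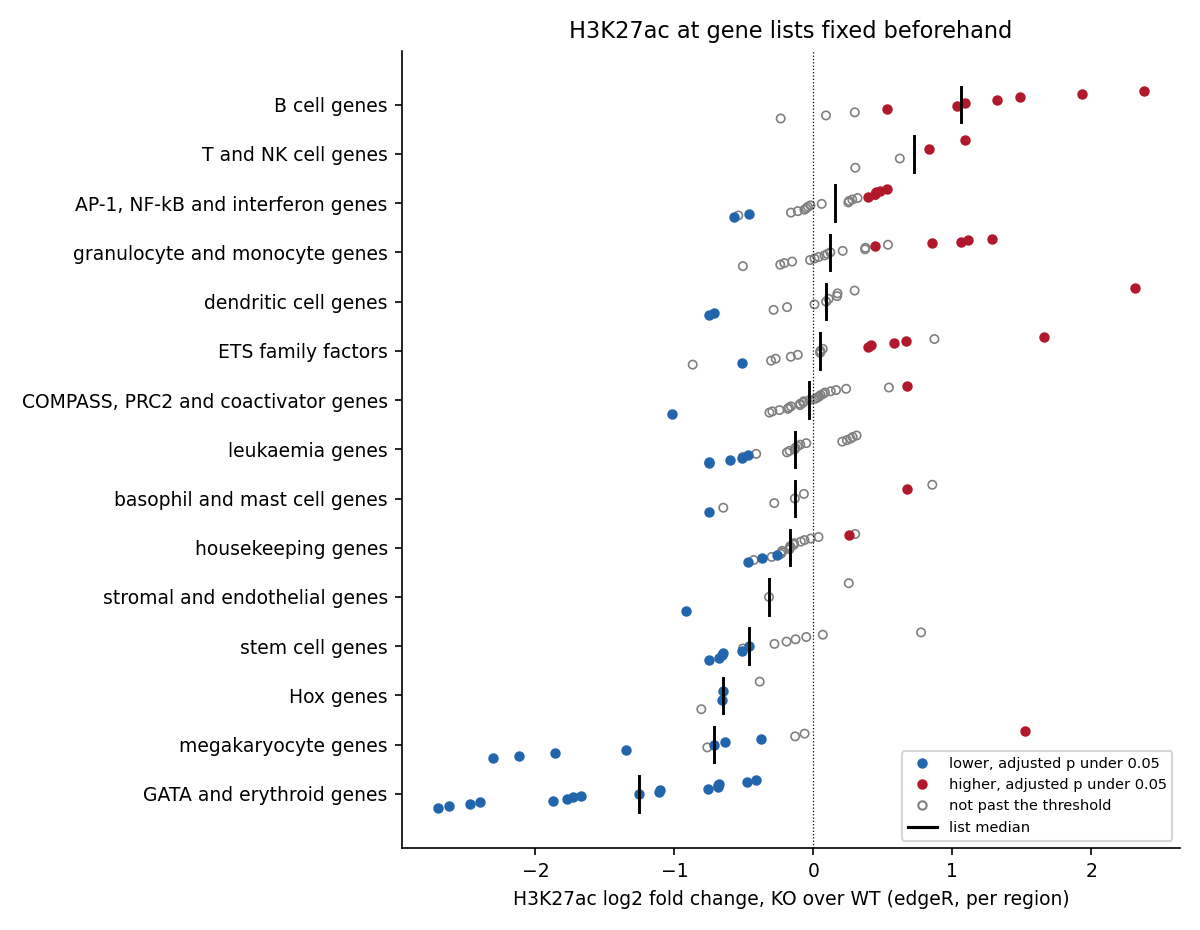
H3K27ac log2 fold change (KO over WT, n = 2 and 2) of the regions at members of each gene list, 1 point per region. Filled points passed edgeR at an adjusted p under 0.05, and bars mark list medians. Per covered length the medians of the megakaryocyte list and of the T and NK cell list change sign. Among called genes named in the text, so do the points of Vwf, Thbs1, Itga2b, Cd14, Cd3d, Spib, Irf1 and Hnrnpa2b1. Of these, Cd3d, Spib and Irf1 go below 0 but stay above the median of all tested regions on that scale (-0.071).

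B cell genes rose in H3K27ac in 7 of 10 regions, with no region lower (8 higher when adjusted over the list alone). Pou2af1 rose from 12.7 ± 2.46 to 66.9 ± 24.5 CPM (2.38, SE 0.283, edgeR adjusted p = 0.00159), and the interleukin 7 receptor gene Il7r from 23.7 ± 6.27 to 67.0 ± 13.9 CPM (1.48). Cd22 (1.32), Cd79b (1.09), Blnk (1.03) and Cd79a (0.53) rose, whereas Rag2 (-0.23), Dntt (0.09) and the region shared by Vpreb1 and Igll1 (0.30) did not pass. Cd79a lost its call without WT replicate 2 (0.0581) and Cd79b without WT replicate 1 (0.0675). Camera gave an adjusted p of 3.41e-05 (5.69e-05 per covered length, median 0.49 against 1.06; adjusted p = 0.389 with an estimated correlation), where Il7r (0.97, 0.0713), Cd22 (0.315, 0.561), Cd79b (0.755, 0.132), Blnk (0.67, 0.151) and Cd79a (0.09, 0.837) lost their calls per covered length. Among T and NK cell genes, the region of Cd3d and Cd3g rose (0.83) and so did Lck (1.09), the T cell receptor kinase, while Cd5 (0.30) and Il2rb (0.62) did not pass. Cd3d and Lck lost their calls without WT replicate 1 (0.0714 and 0.115), WT replicate 2 (0.142 and 0.195) or KO replicate 1 (0.121 and 0.225), where Lck was 0.67. That list had 2 of 4 regions higher (2 also when adjusted over the list alone) and did not pass camera (adjusted p = 0.207), and per covered length its median went from 0.73 to -0.21.

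Granulocyte and monocyte genes rose in 5 of 19 regions, and none fell with edgeR across all regions (5 higher and 1 lower when adjusted over the list alone). Cebpe, which drives granule maturation, rose from 91.8 ± 0.77 to 191.7 ± 0.74 CPM (1.06, SE 0.079, edgeR adjusted p = 0.000402), and Gfi1, a repressor needed by neutrophils, from 98.9 ± 8.92 to 241.3 ± 5.58 CPM (1.28). Fcgr3 (0.85), Cd14 (1.11) and Csf2ra (0.44) rose. Csf2ra lost its call without WT replicate 2 (adjusted p = 0.0577) or KO replicate 1 (0.0513). Cd14 lost its call with DESeq2 (0.0603) and without WT replicate 1 (0.0765), WT replicate 2 (0.0925) or KO replicate 1 (0.106), and went to -0.16 per covered length, where Gfi1 (0.23, 0.441), Fcgr3 (0.07, 0.911) and Csf2ra (0.28, 0.418) also lost their calls. The early myeloid genes Cebpa (0.10), Mpo (0.12), Irf8 (-0.02) and the region of Elane and Prtn3 (-0.24) did not pass, nor did Ccr2 (-0.51, adjusted p = 0.0537). Camera gave an adjusted p of 0.0123 (adjusted p = 0.496 with an estimated correlation, 0.374 per covered length, and 0.109 without WT replicate 1).

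ETS family factors moved both ways, 5 regions up and 1 down of 15 (5 higher and 3 lower when adjusted over the list alone). Spi1, encoding PU.1, the main driver of myeloid fate, rose from 347.9 ± 19.2 to 457.9 ± 15.3 CPM (0.40, SE 0.076, edgeR adjusted p = 0.01). Fli1 rose from 452.5 ± 34.8 to 604.7 ± 0.87 CPM (0.42, SE 0.078, adjusted p = 0.00919), Ets2 by 0.66 and Spib by 0.58. Spi1 (adjusted p = 0.0669) and Fli1 (0.0541) lost their call without WT replicate 1, Spib without WT replicate 1 (0.0725) or 2 (0.0611) and Ets2 without WT replicate 2 (0.0745) or KO replicate 1 (0.0827). Per covered length 0 of the 15 regions were called higher or lower with edgeR. Spi1 (0.08), Fli1 (0.12), Spib (-0.01) and Ets2 (0.07, edgeR adjusted p = 0.928) were near 0 on that scale, and Elk3 was at -0.40 (0.304). Elk3 fell (-0.51, lost without WT replicate 1 at 0.114, WT replicate 2 at 0.166 or KO replicate 2 at 0.155, where it was -0.32), whereas Erg (0.87, adjusted p = 0.0952), Etv5 (-0.87, adjusted p = 0.0504), Etv6 (0.07), Elf1 (-0.27) and Gabpa (-0.16) did not pass. The list as a whole did not pass camera (adjusted p = 0.105, median 0.05; adjusted p = 0.496 with an estimated correlation), and per covered length its median (0.04) and mean (-0.04) differed in sign.

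**Figure D2:**
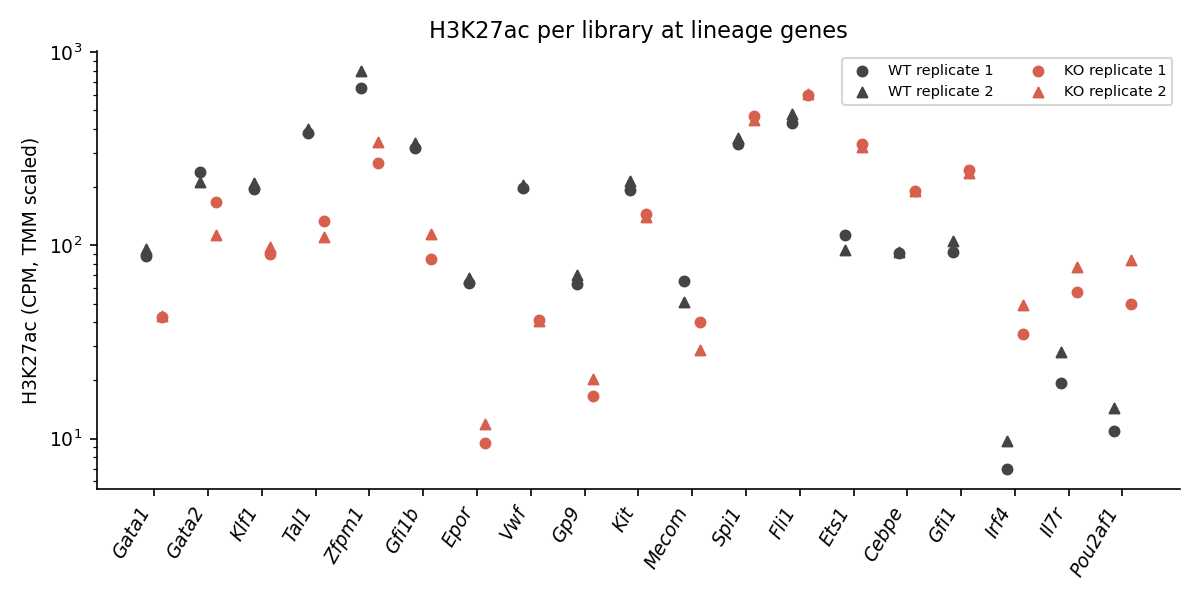
H3K27ac (CPM, TMM scaled, log axis) in each library at lineage genes. WT libraries are grey and KO libraries red, and symbols mark replicates. Per covered length Vwf changes sign.

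Stem cell genes fell in 6 of 13 regions (6 lower and 1 higher when adjusted over the list alone). Kit, the stem cell factor receptor, fell from 204.2 ± 15.2 to 143.3 ± 4.02 CPM (-0.51, SE 0.086, edgeR adjusted p = 0.00587). Cd34 (-0.68), Mecom, a stem cell self-renewal factor (-0.75), Meis1 (-0.46), the region of Hoxa3 to Hoxa10 (-0.66) and that of Hoxb3 to Hoxb6 (-0.65) fell. Runx1 (-0.05), Hlf (-0.28) and Etv6 did not pass. Of these calls only Kit kept its call without each of the 4 libraries. Per covered length 0 of the 13 regions were called lower with edgeR. Kit was at -0.615 there (adjusted p = 0.0625) and the region of Hoxa9 at -0.625 (0.0538). The stem cell list (adjusted p = 0.0967) and the Hox list (0.105, 2 of 4 regions lower, 3 when adjusted over the list alone) did not pass camera. Among dendritic cell genes Irf4 rose (8.33 ± 1.96 to 42.0 ± 10.2 CPM, 2.31), while Flt3 (-0.75) and Clec9a, in the region of Clec1b (-0.72), fell (11 regions, camera adjusted p = 0.846; 1 higher and 3 lower when adjusted over the list alone). Flt3 lost its call without WT replicate 1 (0.107) or WT replicate 2 (0.0957), and Clec9a as given for Clec1b above. Of 7 basophil and mast cell regions, that of Il4 rose (0.67) and Ms4a2, an IgE receptor chain, fell (-0.75; camera adjusted p = 0.955, the same 1 and 1 when adjusted over the list alone). Of 3 stromal and endothelial regions Kdr fell (-0.92; camera adjusted p = 0.846; 1 higher and 1 lower when adjusted over the list alone), but not with DESeq2 (0.134), with islands in at least 2 libraries (0.145) or without any 1 library (0.0909 to 0.204).

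Leukaemia genes fell in 5 of 19 regions and none rose with edgeR across all regions (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.213). They were Myc (183.9 ± 2.07 to 121.5 ± 6.42 CPM, -0.60, SE 0.082), the p53 gene Trp53 (-0.75), Npm1 (-0.47), Flt3 and Kit. Npm1 lost its call with DESeq2 (0.0566), without TMM (0.0673) and without any 1 library (0.0593 to 0.21). Of 23 regions of COMPASS, PRC2 and coactivator genes, Dpy30, a COMPASS subunit, fell (292.9 ± 49.9 to 145.0 ± 3.19 CPM, -1.02) and Smarca4 rose (0.68), with the same counts when adjusted over the list alone (camera adjusted p = 0.846). Kmt2d (0.05), Ep300 (0.01) and Ezh2 (-0.18) did not pass. In the AP-1, NF-kB and interferon list, Fos (0.45), Nfkb2 (0.48), Nfkbia (0.45), the region of Tnf (0.39) and Irf1 (0.53) rose and Egr1 (-0.46) and Il1b (-0.57) fell, of 20 regions (camera adjusted p = 0.24). Of 19 housekeeping regions Gapdh rose (0.26) and Rplp0 (-0.47), Rpl13a (-0.37) and Hnrnpa2b1 (-0.26) fell, while Actb (0.04) did not pass (camera adjusted p = 0.238; 1 lower when adjusted over the list alone). Myc, Trp53, Kit, Dpy30 and Egr1 kept their calls without each of the 4 libraries, and each other call named in this paragraph ended without at least 1 of them. Per covered length these 5 lost their calls too: Myc (-0.60, adjusted p = 0.137), Trp53 (-0.23, 0.404), Kit (-0.61, 0.0625), Dpy30 (-0.165, 0.569) and Egr1 (-0.15, 0.722). On that scale Irf1 (-0.04) and Hnrnpa2b1 (0.11) changed sign, and so did Cd3d (-0.03). Irf1 and Cd3d stayed above the median of all tested regions there (-0.071).

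Presence and absence of H3K27ac islands at gene ends added further red cell and B cell genes. Lost in KO were Car1 (69.55 and 85.8 rpm in WT), Rhag, the Rh blood group scaffold (92.7 ± 13.4), and Hba-a1 of the erythroid list, and Gp6 of the megakaryocyte list. With 5 kb windows Rhag was no longer lost, while Car1, Hba-a1 and Gp6 still were. Kel, the Kell blood group protease (91.8 ± 8.03), Steap3, an erythroid ferrireductase (167.8 ± 4.36), Rnf222 (112.6 ± 4.2), Mylk3 (105.9 ± 12.2) and Tcf25 (90.7 ± 16.2) were among the strongest losses. Gained were Pax5, the B cell commitment factor (82.9 ± 23.7), Rag1 and Bank1 of the B cell list (Fisher's exact test, two-sided, adjusted p = 0.000244). S100a9, Camp and Fcgr3 of the granulocyte list were gained too (adjusted p = 0.0023). With 5 kb windows Fcgr3, whose nearby region held islands in all 4 libraries, was no longer gained (adjusted p = 0.0242). Among the strongest gains were Cnn1 (163.4 ± 34.0) and Dcaf1 (151.4 ± 5.87). Losses in the erythroid (adjusted p = 0.205), megakaryocyte (0.251) and Hox lists (Hoxb2 and Hoxb6, 0.248), and the gain of Cd2 and Lef1 in the T and NK cell list (0.175), did not pass. Esam, Runx2 (both lost), Cdkn2a and Pax2 (both gained) were among the other list members.

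In all, 288 gene ends lost and 246 gained H3K27ac, while 11321 of 21887 (51.7%) kept it in all 4 libraries. The other pairings of the 4 libraries gave 43 and 25, and 8 and 79. At equal list lengths the counts were 243 and 377. A wide island can end just inside a window: of the 40 strongest lost or gained gene ends of both marks, 6 kept their difference with 5 kb windows, among them Kel, Pgam2, Pax5 and, in H3K27me3, Actn2. With 1 library left out the definition is looser and every count was higher, most for lost gene ends without KO replicate 1 (477) and for gained ones without WT replicate 2 (386) or KO replicate 2 (450).

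**Figure D3:**
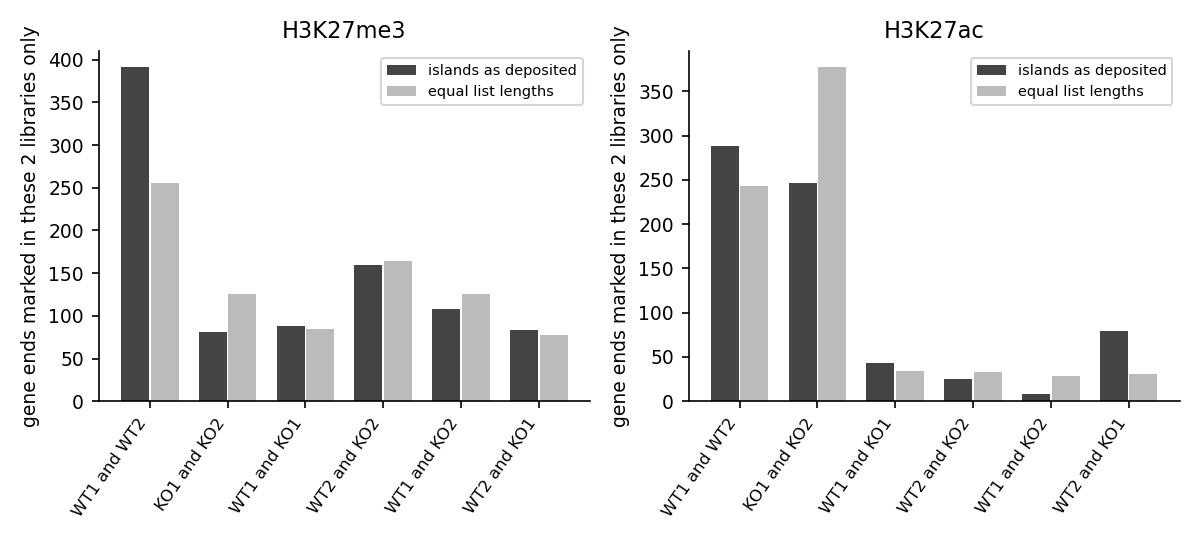
Gene ends marked in 2 of the 4 libraries only, for the genotypes and the other pairings, with islands as deposited and at equal list lengths. For H3K27ac equal lengths turn the excess of losses into an excess of gains.

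H3K27me3 gave a single call. The region at Tnrc18, a chromatin reader gene (chromosome 5, 142810801 to 142827400), was the only one of 6771 called, falling from 279.4 ± 54.6 to 70.0 ± 1.23 CPM (-1.996, SE 0.244, n = 2 and 2, edgeR adjusted p = 0.0484). No region was called higher with edgeR, and DESeq2 called 16 higher and 17 lower. The number of calls cannot be compared directly with H3K27ac, since power differed. The median SE was 0.371 (H3K27ac 0.183), and 15% of simulated 2-fold changes were recovered (H3K27ac 75%). Quartiles of the log2 fold change were -0.25 and 0.26 (H3K27ac -0.295 and 0.323), but these hold noise as well as change. Given the larger SE of H3K27me3, their likeness does not show changes of like size. At an unadjusted p under 0.05 edgeR gave 517 of 6771 regions, against 7223 of 18820 in H3K27ac. Of the 517, 260 were higher and 257 lower. The other pairings, with 1 WT and 1 KO library on each side, gave 201 and 260 in both directions. Tnrc18 lost its call per covered length (-0.64, adjusted p = 0.997) and without WT replicate 1 (0.15), WT replicate 2 (0.406) or KO replicate 1 (0.392), and without KO replicate 2 edgeR called 1 higher and 6 lower regions. Among list members, Gata2 had 281.2 ± 66.2 CPM in WT and 462.7 ± 6.45 in KO (0.72, SE 0.188, edgeR adjusted p = 0.384), Sptb 183.4 ± 2.52 and 295.0 ± 80.5 (0.69) and Gp9 26.3 ± 2.01 and 61.2 ± 1.21 (1.22, adjusted p = 0.53). None passed with edgeR across all regions, and Gata2 and Sptb did so when adjusted over the list alone (2 of 4 erythroid regions higher, but 0 or 1 without any 1 library and 1 per covered length).

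As groups, the erythroid (4 regions, median 0.60), stem cell (11 regions, 0.16) and Hox lists (8 regions, 0.14) passed camera upwards in H3K27me3 (adjusted p = 0.0445, 0.0445 and 0.0492), with Hlf (0.97), Hoxa4 (1.07) and Meis1 (0.54) among members above 0. None of the 3 lists passed with an estimated correlation (adjusted p = 0.734 with an estimated correlation), per covered length (0.882 for the erythroid list and 0.964 for both others) or without WT replicate 1, KO replicate 1 or KO replicate 2 (lowest 0.156). Of regions at gene ends, the Hox C cluster held the most signal (7278 ± 471 and 7496 ± 120 CPM, 0.04) and Cdkn2a with Cdkn2b, a known Polycomb target locus, had 838.3 ± 251.1 and 856.0 ± 35.1 (0.03). The B cell factor genes Ebf1 (-0.40) and Pax5 (-0.26) did not pass. Megakaryocyte (adjusted p = 0.519), granulocyte (0.519), T and NK cell (0.546), dendritic cell (0.452), stromal (0.452), leukaemia (0.599), developmental Polycomb target (0.452, 48 regions) and AP-1 lists (0.93) did not pass. ETS, B cell, basophil, COMPASS and housekeeping genes had fewer than 3 tested regions in H3K27me3.

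H3K27me3 islands disappeared from more gene ends than they appeared at. Lost were Fli1 (41.55 and 60.3 rpm in WT), Kmt2a, Bcl2 and the megakaryocyte genes Itgb3 and Thbs1, each with no island in KO, and gained was Ncr1, an NK cell receptor gene (29.0 and 25.1 in KO). The strongest losses were at Zfp511 (447.6 ± 64.4), Zc3h3 (427.1 ± 50.1), Hadha (265.7 ± 61.3) and Nfatc3 (158.4 ± 33.4), and strong gains were at Bsg (176.4 ± 13.4), Zfp804a (86.5 ± 2.39), Gpr155 (74.1 ± 7.23) and the imprinted gene Zdbf2 (66.2 ± 2.2). With 5 kb windows 6 of the strongest lost or gained gene ends of both marks kept their difference and 34 did not. Most differences at these strongest gene ends therefore depend on where an island ends near the window. The list members Fli1, Kmt2a, Bcl2, Itgb3 and Thbs1 were still lost with 5 kb windows, and Ncr1 was still gained. Over all genes 489 gene ends were lost and 105 gained with these windows. In all, 391 gene ends lost and 81 gained the mark, with 88 and 159, and 108 and 83, for the other pairings. At equal list lengths 256 were lost and 126 gained, with Fli1, Kmt2a and Bcl2 still lost but Itgb3 and Thbs1 not. Without 1 library, a looser definition, the lost ranged from 567 (KO replicate 1 left out) to 837 (WT replicate 1) and the gained from 157 (WT replicate 1) to 291 (KO replicate 1). Developmental Polycomb targets kept the mark in all 4 libraries in 50 of 50 genes and Hox genes in 38 of 39. No list passed Fisher's exact test (two-sided). For losses the lowest exact values were the developmental targets (p = 0.0501) and megakaryocyte genes (p = 0.0676), both at an adjusted p of 0.507, and for gains the T and NK cell genes through Ncr1 (p = 0.0371, adjusted p = 0.519).

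Hjurp, a centromere chaperone gene, held the strongest UTX islands at a gene end in WT progenitors (1414 ± 17.4 rpm, n = 2). Next were Irf2bp2 (551.3 ± 52.2), the corepressor gene Sin3a (472.6 ± 60.8), Zfp36l2, an RNA decay factor of progenitors (442.0 ± 102.0), Cdkn1b, encoding the cell cycle inhibitor p27 (436.1 ± 67.8), Rhof with its neighbour Setd1b (413.9 and 396.8), B9d2 (383.8), Kmt2d, encoding the methyltransferase partner of UTX (381.8 ± 69.7), and Trim8 (381.1 ± 60.3). UTX occupied 7553 gene ends (34.5%), of which 98.1% had H3K27ac in both WT libraries and 12.8% H3K27me3. Of the fixed lists, 12 of 22 erythroid genes, 10 of 16 ETS genes, 19 of 23 COMPASS genes, 17 of 20 housekeeping genes, 12 of 23 leukaemia genes and 13 of 23 AP-1 genes were occupied. So were 3 of 17 megakaryocyte, 7 of 24 stem cell, 6 of 25 granulocyte, 2 of 16 B cell and 0 of 17 T and NK cell genes, and no test compared the lists. UTX islands met H3K27ac of both WT libraries in 73.4% (95% interval 72.6 to 74.1) and 71.7% (71.0 to 72.3) of cases, against 0.77% (0.52 to 1.14) of IgG islands. H3K27me3 was met by 9.85% and 7.33%, against 8.84% of IgG islands. The 2 UTX libraries shared 57.0% and 44.1% of their islands.

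Regions that lost H3K27ac were occupied by UTX more often than others: 52.3% of the 2631 lower regions, among them those of Gata1, Tal1, Klf1, Epor and Kit, against 36.01% of the rest (Fisher's exact test, two-sided, odds ratio 1.95, p = 9.41e-56). Of the higher regions 30.0% were occupied, against 39.4% of the rest (the same exact test, odds ratio 0.66, p = 2.81e-18), and those of Ets1, Cebpe, Gfi1 and Irf4 were not. These exact tests were not matched for strength: lower regions had a median of 72.98 CPM in WT and 11.4 kb, higher ones 24.11 CPM and 8.6 kb, and all tested regions 31.7 CPM and 7 kb. Over all regions, matched for strength, the mean log2 fold change of UTX regions lay below that of others by 0.088 (matched difference -0.088, permutation p = 1e-05, the smallest possible; -0.165 without matching). This difference was -0.0296 with UTX replicate 1 alone and -0.272 with UTX replicate 2 alone. It reversed to 0.0461 without KO replicate 1 (permutation p = 0.00057), was -0.0163 (p = 0.236) without KO replicate 2, and was -0.0021 (p = 0.799) per covered length. In H3K27me3 the matched difference was 0.061 (permutation p = 0.00111), but -0.0803 without WT replicate 1 (p = 0.00011), 0.029 (p = 0.15) without KO replicate 1 and -0.0593 (p = 1e-05) per covered length.

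Opposite changes of presence at the same gene were few. Clstn3, Slc18b1 and Slc38a5 lost H3K27ac and gained H3K27me3 (3 genes against 0.67 from chance, odds ratio 4.75, Fisher's exact test, two-sided, p = 0.0297, adjusted p = 0.0594). The reverse held for 12 genes, including the testis factor gene Ctcfl, Grhl1 and the imprinted gene Peg12 (6.94 from chance, odds ratio 1.86, the same exact test, p = 0.0683, adjusted p = 0.0683). These genes are named because of their small number, after their values were seen. With 5 kb windows the odds ratio of the 1st pair was 6.25 (adjusted p = 0.0037) and of the 2nd 1.09 (0.846), and at equal list lengths 8.43 (8.76e-05) and 2.06 (0.0456). On the X chromosome the median H3K27me3 log2 fold change was 0.19 over 442 regions, against -0.08 to 0.06 on the autosomes, and the X held 6.11 ± 1.62% of H3K27me3 island reads in WT and 8.27 ± 1.60% in KO (exact permutation p = 0.667, with WT replicate 2 at 7.26% above KO replicate 1 at 7.14%).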

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

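Chosen after seeing the data were the tests per covered length of the UTX comparison and the lists, the lists without each library, whole gene spans and regions without IgG islands. Motif comparisons and their alternatives were not run. Libraries left alone in a genotype were assumed to vary like the others. Where no construction is named, the cause was not tested. Named H3K27ac genes kept their sign in every alternative in 79 of 88 cases, and 54 kept their call in all but the covered length. The 9 that reversed did so per covered length: Cd14 -0.16, Cd3d -0.03, Hnrnpa2b1 0.11, Irf1 -0.039, Itga2b 1.06, Ppp3cc -0.11, Spib -0.012, Thbs1 0.15 and Vwf 0.20. The median of all tested regions was -0.071 on that scale, so Cd3d, Irf1 and Spib did not fall relative to it. H3K27me3 gene ends gained were 44 with the stricter threshold, and 126 (lost 256) at equal lengths, where H3K27ac gains were 377. Without 1 library, a looser definition that raises each count, H3K27me3 losses ranged from 567 to 837 and gains from 157 to 291, H3K27ac losses from 343 to 477 and gains from 316 to 450. UTX gene ends fell to 1282 where islands had to cover 50% of the window. H3K27ac regions lower were 5225 with islands in at least 2 libraries, and per covered length 79 were higher and 259 lower. Without 1 library 1254 to 1423 were higher and 1395 to 2022 lower, fewer samples being tested. H3K27me3 regions higher were 16 with DESeq2 and 3 per covered length, and 0 to 1 without 1 library. Per covered length the median log2 fold change of all tested H3K27me3 regions was 0.109. Those lower were 17 with DESeq2, 0 without TMM, with islands in at least 2 libraries, merged within 1 kb or without IgG islands, and 0 to 6 without 1 library.

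UTX regions differed from others in H3K27ac by -0.0021 per covered length (permutation p = 0.799) and by -0.2413 to 0.0461 without 1 library, reversed without KO replicate 1, and in H3K27me3 by -0.0593 per covered length (reversed) and by -0.0803 to 0.2066, reversed without WT replicate 1. With an estimated correlation camera gave 0.389 for erythroid, megakaryocyte and B cell H3K27ac, 0.496 for granulocyte H3K27ac, and 0.734 for erythroid, stem cell and Hox H3K27me3. With 5 kb windows erythroid, stem cell, Hox and leukaemia H3K27me3 (the last now downwards) had 0.158, 0.0739, 0.0739 and 0.93. At equal lengths Hox and megakaryocyte H3K27me3 (now downwards) had 0.216 and 0.849. Per covered length H3K27me3 lists had 0.882 (erythroid) and 0.964 (10 others, 8 of them the other way), and in H3K27ac megakaryocyte had 0.974, granulocyte 0.374, T and NK cell 0.919, basophil 0.974 and COMPASS 0.919, the last 3 the other way. Without 1 library adjusted p-values in H3K27me3 ranged from 0.00697 to 0.285 (erythroid), 8.39e-05 to 0.94 (stem cell), 0.000584 to 0.94 (Hox), 0.281 to 0.931 (T and NK cell), 0.108 to 0.741 (leukaemia), 0.285 to 0.913 (AP-1) and 8.39e-05 to 0.973 (developmental), the direction differing between the libraries left out in the last 4. The developmental list passed upwards without WT replicate 2 (8.39e-05, median 0.18) and downwards without WT replicate 1 (0.019, median -0.11). In H3K27ac they ranged from 0.00129 to 0.109 (granulocyte), 0.0101 to 0.328 (stem cell), 0.00916 to 0.604 (T and NK cell), 0.585 to 0.984 (dendritic cell), 0.585 to 0.962 (basophil), 0.0403 to 0.284 (Hox) and 0.353 to 0.975 (COMPASS), the direction differing for dendritic cell, basophil and COMPASS. Both marks together, lost H3K27ac with gained H3K27me3 had an odds ratio of 6.252 with 5 kb windows and 8.43 at equal lengths, where gained H3K27ac with lost H3K27me3 had 2.064.

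A block of replicate numbers took H3K27me3 lists of erythroid, stem cell and Hox genes to 0.0524 each, stem cell H3K27ac to 0.0481 and lower H3K27me3 regions to 0, and changed no other call of the named H3K27ac genes. Deviations of WT replicate 1 and KO replicate 1 correlated across regions, which are not independent, at 0.046 (H3K27ac) and -0.051 (H3K27me3), and nothing in the labels pairs them.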

Other observations

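Other red cell genes fell in H3K27ac beside those of the erythroid list. A list of haem synthesis and red cell membrane genes, chosen after the results of the fixed lists were seen but before its own values were, had 14 of 16 regions lower with edgeR (16 when adjusted over the list alone, median -1.10). Rhd, the Rhesus antigen gene (-3.08, SE 0.533), Tspo2, a cholesterol carrier of erythroblasts (-2.71), the water channel gene Aqp1 (-2.69) and Hemgn (-2.31) fell the most. The haem enzymes Cpox (-1.64), Alad (-1.29), Fech (-1.15), Uros (-1.03) and Urod (-0.67) fell, while Ppox (-0.20) and Xk (-0.41) did not pass. Camera gave an adjusted p of 4.01e-18 (3e-08 per covered length with a median of -0.62, and 0.202 with an estimated correlation). With edgeR per covered length 4 of the 16 regions were called lower and all 16 lay below 0. Urod (-0.036) and Cpox (-0.307) were much nearer 0 there than over whole islands.

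Further B cell genes rose in 8 of 13 regions and fell in 2: Ikzf3, encoding Aiolos (1.76, SE 0.089), Fcrla (1.62), the kinase gene Blk (1.60), Cd72 (1.14), Bach2 (1.03), Foxo1 (0.99), Syk (0.61) and Cd37 (0.38) rose, and Bcl11a (-0.92) and Pou2f2 (-0.84) fell. Camera gave an adjusted p of 6.02e-05 (0.128 per covered length, and 0.202 with an estimated correlation). With edgeR per covered length 1 of the 13 regions was called higher and 1 lower. Among eosinophil genes Epx (2.08) and the region of Prg2 and Prg3 (1.71) rose and Siglecf (-0.44) fell. That list of 5 regions did not pass (adjusted p = 0.0654, 0.202 with an estimated correlation), and its median (-0.16) and mean (0.57) differed in sign. Cebpz, put into the eosinophil list by mistake, was taken out after a first run.

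The tests of island extent and depth were chosen after the H3K27ac result was seen. Over the 4889 called regions the median change per covered base, signed by the call, was 0.304 (quartiles 0.029 to 0.57), against 0.856 over whole islands, and 77.3% kept their sign. How far islands were called may therefore account for part of the H3K27ac change, and its share cannot be told apart from that of signal within islands. The pairing that follows depth called 0 regions with edgeR (93 at an unadjusted p under 0.05). It puts 1 WT and 1 KO library on each side, so the genotype difference widens its spread and few calls follow. Whether depth contributed is therefore not decided by this test. Loss of UTX itself could underlie the rest, which stays open.

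For lower erythroid and higher B cell H3K27ac, the comparison of lineages was chosen after the result was seen, and the haem and membrane genes before their values were. B cell regions lay 0.821 above those of granulocyte, monocyte, dendritic, basophil and mast cell genes (0.993 ± 0.829 over 10 regions and 0.171 ± 0.621 over 37; 0.557 per covered length), but these are the regions of the pattern itself and not independent (adjusted p = 0.389 for the B cell list with an estimated correlation), so a smaller share of erythroid cells with nothing else changed stays open. A different mix of progenitor cells could give the 14 lower haem and membrane regions, but these did not fall by 1 common factor (-3.08 to -0.20, heterogeneity Q 393.1, df 15). These explanations and a change within cells cannot be told apart here, and either may follow from loss of UTX.

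For the excess of lost H3K27me3 gene ends, the test of list length was chosen after the result was seen and that of island strength before. Shorter KO island lists may account for much of it: at equal lengths the ratio of lost to gained was 2.03, against 4.83 as called and 1.93 for the highest other pairing. WT islands at lost gene ends had a median strength rank of 46.17%, against 84.4% where all 4 libraries held islands. Gained gene ends had 40.02%, and those of the other pairings 32.58% to 44.27%. The rank at lost gene ends fell between the limits set beforehand for and against weak islands. Weak islands near the threshold could therefore also contribute, which this test leaves undecided. These explanations and a loss of the mark in KO cannot be told apart. UTX removes H3K27me3, so its loss would directly give gains of the mark rather than losses. Whether loss of UTX led to these losses by another route was not tested and stays open.

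One further test was written before its values were seen: at gene ends holding both marks, H3K27ac and H3K27me3 may move in opposite directions. Across 1430 region pairs of 1573 genes, which are not independent, Spearman rho was -0.226 (permutation p = 1e-05, the smallest possible), -0.225 to -0.178 without each library and -0.114 per covered length. Where H3K27ac was lower, H3K27me3 lay above 0 in 149 of 252 pairs (59.1%), and where it was higher, below 0 in 136 of 196 (69.4%). The share over all pairs is not given here. The median H3K27me3 log2 fold change was 0.12 and -0.136 in these 2 sets, against -0.002 over all tested H3K27me3 regions.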
